A study of Cyanidioschyzon merolae with 8 samples.

How the data were processed

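RNA was sequenced from wild-type cells of strain 10D of Cyanidioschyzon merolae, a unicellular red alga of hot acidic springs. The 8 libraries fall into 4 groups of 2 biological replicates: cells given blue light, their dark control, cells given red light, and their own dark control. Per the labels' protocols, cultures grew in acid medium at pH 2.3 and 42 °C under continuous light of 100 µmol m-2 s-1. Cells of the blue light experiment were then kept dark for 36 h and given blue light of 15 µmol m-2 s-1 for 30 min. The wavelength given for the measurement of intensity is 365 nm for the blue and 630 nm for the red experiment. Cells of the other experiment, also kept dark for 36 h, received red light for 30 min, at an intensity that the sources used here do not give. RNA was selected on oligo(dT) beads, made into libraries with the TruSeq mRNA kit and sequenced as pairs of 75 bp reads on a MiSeq. The labels mention no strand-marking step, so reads of genes on opposite strands may not be told apart.

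The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.32, TopHat, TopHat2 2.0.5 and Cuffdiff. The genome build and the annotation are not given in the sources used here. The deposited table stacks 2 comparisons, each of a light with its dark control, over 5092 gene IDs, of which 1 names no gene. The authors deposited expression as FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 value per condition in which the replicates are already combined. The authors' deposited log2 ratio is light over dark control, with text in place of a number where a condition is listed at 0. It was therefore computed again from the deposited FPKM, and the largest difference from the deposited value was 4.53e-05. The authors' deposited test statistic is a score that is 0 where a gene was not tested, and was not used further. The authors' deposited p-value and q-value are listed per gene and comparison, but the q-values were not adjusted within each comparison. CMO306C has the authors' p-value of 0.00125 and q-value of 0.00636 under both lights. Its Benjamini-Hochberg value within the blue comparison alone is 0.00504. The q-values also differ from Benjamini-Hochberg values over both comparisons, by up to 0.0311, and the set of tests they cover is not given in the sources used here. The smallest p-value is 5e-05, shared by 663 genes of the blue and 634 genes of the red comparison, so p-values do not rank those genes. The authors' own significance mark follows a q-value under 0.01.

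The table has no values per library, so no test on the libraries was made here, and no SD can be given. Each value combines the 2 replicates of its condition. The test foreseen for library counts before the data were examined was replaced by the authors' deposited q-value, as had been set for this case. A gene counts as past the threshold where the authors tested it and their q-value is under 0.05. Sequencing depth is unknown. The low FPKM values did not fall on whole steps from which depth could be read: 25.7% to 27.7% of 300 low values per condition lay within 0.1 of a whole multiple of the best step. Chance gives 20% for a step fixed beforehand and more for the best of many, as taken here. Whether the authors scaled the 4 conditions together is not given in the sources used here, which limits each comparison of levels across the 2 experiments.

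The difference between the responses, the dark controls against each other and the lit cells against each other were computed as differences of log2 FPKM with no pseudocount, over 4390 genes tested under both lights with both ratios. These have no test. The overlap of the responses was set beside the number that independent lists would share. The labels give each light its own dark control, so the comparisons share no libraries. For a gene list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean FPKM, and its 95% interval came from 2000 bootstrap draws over genes. Genes are not replicates, so this interval describes the spread between genes and not between cultures. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The code was checked on simulated normal scores for 4517 genes, the number tested under blue light, with changed genes shifted far enough to be found. There the Benjamini-Hochberg step recovered 99.5% of the changed genes, with 5.24% unchanged genes among its calls. On simulated values for 4438 genes of the red comparison, a list shifted by 1 SD reached percentile 100, and an unshifted list percentile 23.8. Neither run used the deposited ratios or p-values, so they give no power or error rate of the authors' tests.

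Of 23 gene lists set before the data were examined, 21 search gene descriptions. The deposited table holds none, and the reference table of assembly ASM9120v1, which matched 4752 IDs by locus tag, gives no symbol other than the locus tag. Those 21 lists could not be matched, and photosystem, pigment, repair, ribosomal and other functional groups are not reported. They are photosystems and antenna, tetrapyrroles, carotenoids, photolyases and cryptochromes, repair, replication, antioxidants, chaperones, both sets of ribosomal proteins, ribosome biogenesis, tRNA synthetases, carbon fixation, glycolysis, starch, respiration, nitrogen, proteasome, autophagy, histones and transcription factors. The remaining 2 lists search the ID. The chloroplast list took 207 IDs, each of them on the chloroplast in the deposited table. The mitochondrial pattern took 39 IDs, but the table places 5 of these on nuclear chromosomes. A list of the other 34, which lie on the mitochondrial genome, was added after the values had been seen, and both versions are reported. A further set of 9 IDs, also added afterwards, lies between the same neighbouring genes as ribosomal RNA entries of the reference table.

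The rule for named genes, set before the data were examined, took the largest rises and falls by log2 ratio among genes past the threshold with at least 10 FPKM in the higher condition and a description. Genes listed at 0 in a condition were left out of that ranking and counted apart. No minimum was set for the lower condition, so the size and rank of a ratio resting on a few FPKM there are uncertain. Without descriptions, it was limited to 2 rises and 2 falls per comparison, and each ID list adds up to 4 members past the threshold with the smallest p-value. Positions are 1-based and come from the deposited table. In that table, 358 IDs share a locus with another ID, and their values may draw on the same reads. Alternatives tried were a q-value under 0.01, a change of at least 2-fold, a mean FPKM of at least 10, no filter, ratios centred on their median, organelle genes left out, Benjamini-Hochberg values computed again from the deposited p-values, and pseudocounts of 0.1 and 10. A pseudocount of 1, removal of the trend on coding length, leaving out short or shared loci, and choosing chloroplast genes by their test under blue light were added after the data had been seen.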

Results

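Transcript levels of dark-kept C. merolae cells were compared with those of cells given 30 min of blue or of red light. The 8 libraries form 4 groups of 2 biological replicates, and each light has its own dark control. The authors' deposited table gives 1 FPKM value per condition, so the spread between replicates cannot be printed, and the tests are those of the authors. The depth of the libraries is unknown. The median FPKM over all IDs was 94.2 in the dark control of the blue experiment, 92.6 under blue light, 104 in the dark control of the red experiment and 93.0 under red light. The files pair no ID with a gene name, so genes are given by ID.

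The first comparison asked which transcripts change when dark-kept cells receive blue light. In the authors' deposited table, 1002 genes rose and 833 fell among 4517 tested, which is 40.6% of them at a q-value under 0.05. The median change was 2.96-fold for the genes that rose and 2.25-fold for those that fell. Steep changes were mostly rises: 133 genes rose at least 8-fold and 54 fell at least 8-fold. At an unadjusted p-value under 0.05 the table holds 2221 genes.

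Among genes with a value above 0 in both conditions, the largest rises under blue light were those of CMO306C and CMT305C. A further 5 genes past the threshold were listed at 0 in the dark and 3 at 0 under blue light, and have no ratio. CMO306C, on chromosome 15 at 763738 to 764899, went from 4.55 to 953 FPKM, a log2 ratio of 7.71 with q = 0.00636 in the authors' deposited table. CMT305C, on chromosome 20 at 772120 to 773418, went from 4.82 to 776 FPKM with a log2 ratio of 7.33 and q = 0.00175. The largest falls among genes with a ratio were those of CMK010C and CMG099C. CMK010C, on chromosome 11 at 24881 to 26285, went from 1529 to 8.21 FPKM, a log2 ratio of -7.54 with q = 0.00045. CMG099C, on chromosome 7 at 254111 to 255554, went from 420 to 2.35 FPKM with a log2 ratio of -7.48 and q = 0.0337, which does not pass 0.01. The build of these positions is not given in the sources used here, and whether they lie in exons was not analysed here.

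Of the 207 IDs of the chloroplast list, 63 were tested under blue light in the authors' deposited table; 13 rose, 5 fell and 45 did not pass the threshold. Adjusted over the list alone, 13 rose and 4 fell. The median log2 ratio of 60 members with a ratio was 0.28, with a 95% interval over genes of -0.17 to 0.59, at percentile 80.8 of the random lists. CMV135C went from 13.5 to 179 FPKM, CMV129C from 262 to 2343, CMV136C from 9.26 to 76.0 and CMV208C from 262 to 647. Their log2 ratios were 3.73, 3.16, 3.04 and 1.31, and the largest q among them was 0.000817. With loci under 300 bp and loci of more than 1 gene left out, 6 chloroplast genes rose.

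The planned mitochondrial pattern held 5 tested IDs under blue light, of which 3 rose and 1 fell, the same counts when adjusted over the list alone. The 3 that rose, CMX001C, CMX010C and CMX011C, lie on nuclear chromosomes 10, 10 and 8 in the authors' deposited table. The median of the 5 was 1.20 on the log2 scale, at percentile 96.6 of the random lists. Of the 34 IDs of the pattern that lie on the mitochondrial genome 1 was tested, CMW007C, which fell from 114 to 35.6 FPKM with a log2 ratio of -1.68 and q = 0.00045. Another 20 IDs lie on that genome outside the pattern, of which 1 was tested, EPlCMEG00000000026, at 58.4 FPKM in the dark and 78.7 FPKM under blue light with q = 0.374.

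The second comparison asked the same of red light. By the authors' deposited table, 661 genes rose and 1206 fell among 4447 tested, 42.0% of them. At an unadjusted p-value under 0.05 it holds 2312 genes. The median change was 2.87-fold for the genes that rose and 2.19-fold for those that fell. At least 8-fold changes were again mostly rises, 72 against 9. The median log2 ratio of all tested genes was -0.26 under red light and -0.01 under blue light. Among genes past the threshold and changed at least 2-fold with a ratio, 529 rose and 787 fell under red light, 40.2% higher. After the ratios were centred on their median, 644 stood higher and 478 lower, 57.4% higher, because the shift moves genes across the 2-fold bound. Without that bound, 658 genes with a ratio rose and 1206 fell, 35.3% higher. Centring cannot move that split, since the authors' calls were not made again and no called gene lay within the shift of 0. Under blue light 60.5% of the genes past the 2-fold bound stood higher before and 61.2% after centring.

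Among genes with a value above 0 in both conditions, the largest rises under red light were CMN328C and CMO111C. A further 3 genes past the threshold were listed at 0 in the dark and have no ratio. CMN328C, on chromosome 14 at 817565 to 818750, went from 3.12 to 334 FPKM, a log2 ratio of 6.74 with q = 0.0283 in the authors' deposited table. CMO111C, on chromosome 15 at 285367 to 286284, went from 6.96 to 341 FPKM with a log2 ratio of 5.62 and q = 0.00231. Both also rose under blue light, by 6.43 and 5.31 on the log2 scale. The largest falls among genes with a ratio were 2 IDs that lie between the same neighbours as ribosomal RNA entries of the reference table. EPlCMEG00000000070, on chromosome 17 at 782634 to 786206, went from 468 to 13.9 FPKM with a log2 ratio of -5.07. EPlCMEG00000000047, on chromosome 18 at 500241 to 503815, went from 371 to 12.6 FPKM with a log2 ratio of -4.87. All 5 tested IDs of this kind fell under red light, with a median of -4.34, whereas none of 4 tested passed the threshold under blue light, where their smallest unadjusted p-value in the authors' deposited table was 0.213. Ribosomal RNA has no poly(A) tail, and its level in a poly(A)-selected library depends on how the selection worked.

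Tested chloroplast genes were raised together in the red comparison. Of 48 tested in the authors' deposited table, 25 rose and 0 fell, or 27 and 0 adjusted over the list alone. All 48 had a higher FPKM under red light than in the dark control, but which genes were tested depends in part on their red light values. The median log2 ratio of 43 members with a ratio was 2.53, which is 5.76-fold, with a 95% interval over genes of 2.21 to 2.88. It lay above all random lists, whose medians ran from -0.95 to 0.64. Centring would raise it to 2.78. The 159 chloroplast IDs that the authors did not test went the other way, with 72 lower and 46 higher under red light and a median log2 ratio of -0.31 over 90 IDs. Over all 133 chloroplast IDs with a ratio the median was 0.57. The untested IDs had a median of 2.68 FPKM in the dark control and 1.80 under red light. Chosen instead by being tested in the blue comparison, which uses no red light value, 63 chloroplast genes had 56 members higher and 5 lower under red light. Their median log2 ratio over 55 with a ratio was 2.21, with a 95% interval over genes of 1.65 to 2.66. That choice was made after the values had been seen.

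CMV208C went from 42.7 to 979 FPKM under red light and CMV209C from 90.2 to 1949. CMV207C, which shares its locus with another ID, went from 48.1 to 933, and CMV129C from 138 to 1306. Their log2 ratios in the authors' deposited table were 4.52, 4.43, 4.28 and 3.24, each with q = 0.00045. The planned mitochondrial pattern held 9 tested IDs under red light, of which 3 rose and 1 fell, or 4 and 1 adjusted over the list alone, with a median log2 ratio of -0.08 at percentile 53.2. Of its 34 IDs on the mitochondrial genome 5 were tested. CMW007C rose from 19.2 to 55.9 FPKM with q = 0.0103, CMW019C fell from 21.8 to 4.91 FPKM with q = 0.0263, and 3 did not pass the threshold. Outside the pattern, EPlCMEG00000000026 of the mitochondrial genome, named after its values were seen, fell from 33.7 to 8.51 FPKM with q = 0.00468 in the authors' deposited table. The 2 that rose on nuclear chromosomes were CMX010C and CMX011C.

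Chloroplast transcripts differed between the dark controls as well. Over 38 chloroplast genes tested in both comparisons, the median FPKM was 131 in the dark control of the blue experiment, 162 under blue light, 18.4 in the dark control of the red experiment and 127 under red light. Of these 38 genes, 36 were lower in the dark control of the red experiment, with a median log2 difference of -2.55, or 5.87-fold. Of 57 genes tested in the blue comparison with both values, 52 were lower there, with a median of -2.34. Being tested in the blue comparison depends in part on the level in its own dark control, which alone can lower this median. Over all 207 chloroplast IDs, tested or not, the median FPKM was 6.63 in the dark control of the blue experiment and 4.16 in that of the red experiment. The summed FPKM of these IDs was 46391 and 8756. Whether the experiments were scaled together is not known, but the nuclear genes differed by a median of only 0.18 in the other direction. This difference has no test.

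**Figure D1:**
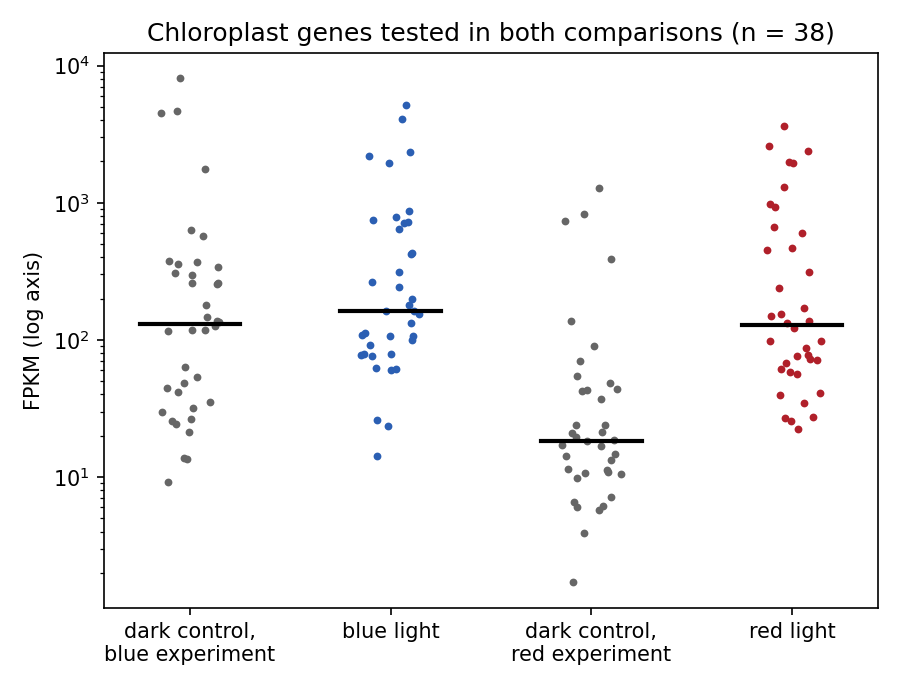
FPKM of the 38 chloroplast genes tested in both comparisons, on a log axis, in the 4 conditions. Each point is a gene and each bar a median; the medians are 131, 162, 18.4 and 127 FPKM, with the lowest in the dark control of the red experiment.

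The change under red light went with gene length. Over 4332 nuclear genes with a known coding length, Spearman's rho between length and the log2 ratio was -0.32 under red light and 0.00138 under blue light, across genes, which are not independent replicates. In the shortest of 4 classes of 1083 genes, 184 rose and 134 fell under red light, and in the longest 77 rose and 514 fell. With the trend removed, 42.5% of the genes changed at least 2-fold in the red comparison stood higher.

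**Figure D2:**
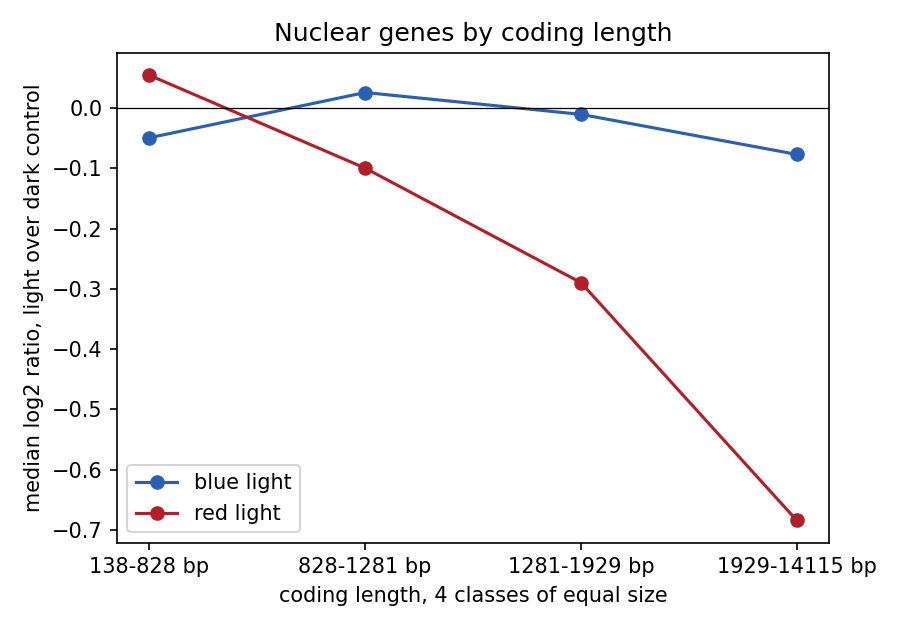
Median log2 ratio of light over dark control in 4 classes of 1083 nuclear genes each, ordered by coding length in bp. The red line falls from 0.05 in the shortest class to -0.68 in the longest, while the blue line stays between -0.08 and 0.03.

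The responses to the 2 lights were then set against each other. Among 4403 genes tested in both comparisons of the authors' deposited table, 468 rose under both lights, against 144 for independent lists, and 509 fell under both, against 223. These are 3.25 and 2.28 times the numbers for independent lists. The shared rises are 48.5% of the genes that rose under blue light and 71.1% of those that rose under red light. The shared falls are 61.5% of the genes that fell under blue light and 42.8% of those that fell under red light. Across 4390 genes, Pearson's r between the log2 ratios was 0.66 and Spearman's rho 0.66. Of 962 genes that rose under blue light, 819 were also higher under red light at any q-value, and of 824 that fell, 755 were also lower. The median red log2 ratio over all tested genes was -0.26, so most genes were lower under red light whatever blue light did.

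**Figure D3:**
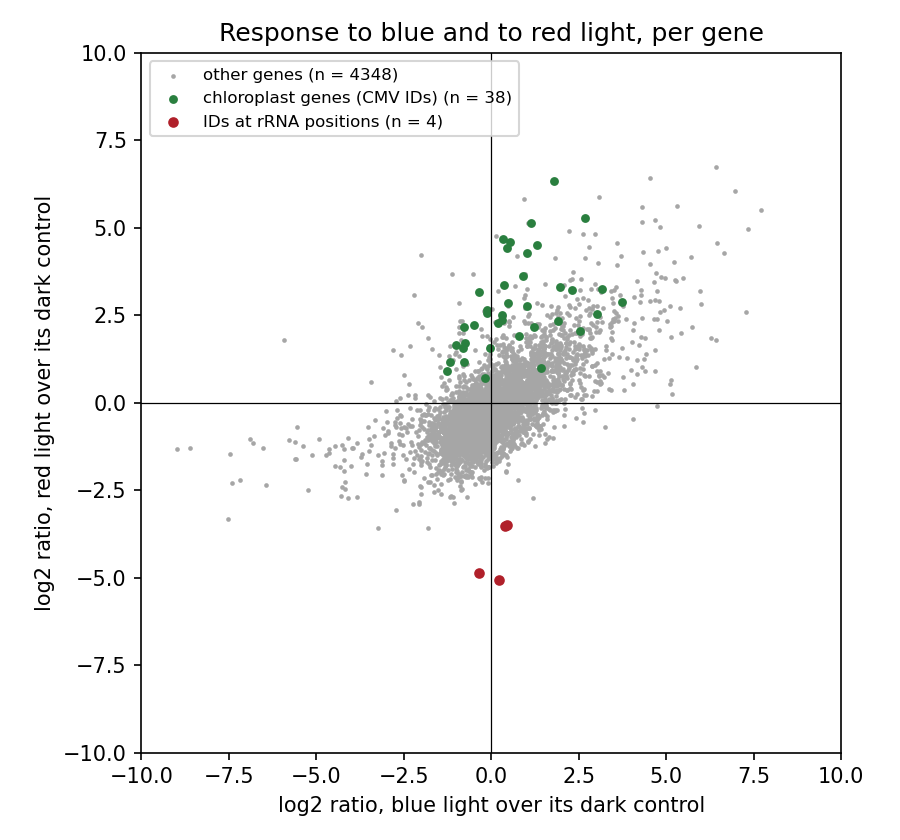
Log2 ratio under red light (vertical) against that under blue light (horizontal) for 4390 genes, a point per gene, with 38 chloroplast genes in green and 4 IDs at ribosomal RNA positions in dark red. The ratios correlate with r of 0.66 across genes; 34 of the 38 chloroplast genes lie above the diagonal and the 4 ribosomal RNA positions below.

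The log2 ratios, taken with their sign, differed by at least 1 between the lights for 1150 genes, 26.2% of those compared. The blue ratio was the higher of the pair for 782 of them and the red ratio for 368, where a smaller fall also counts as the higher ratio. Red ratios lay lower as a whole, by a median of -0.23 for nuclear genes, which tilts this split towards blue light. With ratios centred on their median, 1027 genes differed by at least 1 log2 unit. Of 466 genes that rose under both lights, 316 had the larger change under blue light, and of 507 that fell under both, 269. Of genes past the threshold under blue light, 795 of 962 that rose and 567 of 824 that fell had the larger change under blue light. Of those past it under red light, 330 of 656 that rose and 299 of 1186 that fell did. A gene picked for its change under a light is more often the larger one there by the choice itself. These differences were not tested. The red light intensity is not given, so the size of the responses is not compared at a known equal dose.

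Dark-kept cells of the 2 experiments were not alike. Their FPKM differed at least 2-fold for 1054 of 4390 genes, 525 higher and 529 lower in the red experiment, with a median log2 difference of 0.18. Lit cells differed at least 2-fold for 954 genes, 308 higher and 646 lower under red light, with a median of -0.17. Across genes, log2 FPKM correlated with r = 0.79 between the dark controls and 0.80 between the lit conditions. The correlation was 0.60 between blue light and its dark control, and 0.66 between red light and its dark control. Red light correlated with the dark control of the blue experiment at 0.76, and blue light with that of the red experiment at 0.34. A difference between the lit conditions therefore cannot be read apart from the difference between the experiments, and neither has a test.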

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

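The tests on ribosomal RNA positions, on short loci, on the level above other dark-kept cells, on the blue comparison of length and on the order of genes were chosen after the result was seen.

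Of the genes past the threshold under both lights, 48 changed in opposite directions, 24 each way, against 977 in the same direction. The difference between their ratios was not tested. The widest were CMJ101C, which went from 216 to 54.2 FPKM under blue and from 256 to 4784 FPKM under red light, and CMP086C, with log2 ratios of -2.20 and 3.09. In the other direction CMB087C stood at 1.77 and -1.01, and CMT165C at 2.09 and -0.65. CMP086C was at 3269 FPKM in the dark control of the blue experiment and 105 in that of the red experiment.

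Among IDs that the authors did not test, EPlCMEG00000000024 on chromosome 10 and EPlCMEG00000000076 on the chloroplast were listed at 0 in the dark control and at 11104 and 6402 FPKM under red light. Their loci span 77 and 1578 bp. The opposite also occurs: 2 untested IDs of each comparison are at 0 in the light and at 1000 FPKM or more in the dark. An exact 0 in such a table can be a failed estimate.

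The joint rise of tested chloroplast genes under red light starts from a low dark control. Weaker carry-over of RNA without poly(A) tails into that control should lower the ribosomal RNA positions there as well. The 5 tested under red light did not show this. Their log2 ratio to the other dark control ran from -0.18 to 4.38, with a median of 2.94, where chloroplast genes had an upper quartile of -1.69. Only the loci of 3566 to 3575 bp were clearly higher there, such as EPlCMEG00000000070 at 468 against 22.4 FPKM. The loci of 1793 and 1795 bp were near level, at 126 against 111 and 39.5 against 44.7 FPKM. Loci of like length may hold copies of the same gene, so the 5 may not be independent. Being tested under red light also depends in part on the level in the dark control of the red experiment. EPlCMEG00000000086, at 23.3 FPKM there against 1.86, was not tested under blue light, and the other 4 were tested under both lights. Summed over all 9 positions, tested or not, FPKM was 1027 there against 229, much of it from the long loci. These values argue against weaker carry-over for ribosomal RNA only. Short genes are not the source, since 23 loci of at least 300 bp with 1 gene had a median log2 ratio of 2.55, and 26 such loci chosen by their test under blue light 2.32, and the length trend leaves 2.35 of 2.53 over 29 genes, with an interval of 2.06 to 3.06. Whether red light raised these transcripts above the level of dark-kept cells in general stays open: lit red over dark blue had a median of 0.20 over 38 genes, with an interval over genes of -0.31 to 0.70, and -0.15 over 58 genes chosen by their test under blue light, with an interval of -0.43 to 0.38. Choice by the test under blue light depends in part on the level in dark blue, which alone can lower the latter median. The joint scaling of the experiments is not known. A dark control that differed for reasons of its own may account for the pattern, and the design cannot separate this from red light, since each light has its own control.

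The fall of longer genes under red light is not general to FPKM, since the blue comparison had a rho of 0.00138. It is not set by the expression level, with a rho of -0.34 or lower in each of 5 level classes, nor by genes that respond to blue light, with -0.42 among 2565 genes that did not pass the threshold there. Fragment length or RNA integrity of the red experiment's libraries stays possible. The dark controls differ with length by a rho of 0.20 (interval 0.17 to 0.23), which meets the bound of 0.2 set beforehand only just, and the lit conditions by -0.14. The red ratios followed length and the blue ratios did not. A difference with length between the dark or the lit conditions follows from this, whatever the cause. Meeting the bound therefore does not separate fragment length or RNA integrity from a response of the cells. The deposited table gives no values per library that would.

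Neighbouring nuclear genes changed together, with r of 0.08 under blue and 0.13 under red light over 4145 adjacent pairs. Chance order is argued against by p = 0.0001 in both comparisons, the smallest that 10000 permutations can give. Reads shared between adjoining genes could account for part of it: for 2816 pairs at least 1000 bp apart, r was 0.034 under blue light (permutation p = 0.0716) and 0.085 under red light (permutation p = 0.0002). A biological explanation was not tested.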

How the results depend on the processing

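Removal of the length trend, the added pseudocount of 1 and the limits on short or shared loci were chosen after seeing the data. The choice of chloroplast genes by their test under blue light was also added then. Under the alternatives, 91 values stayed within the bounds set for them (1.5 times for a count, the interval or sampling error for other values), 10 counts fell by more than 1.5 times, 2 values moved and 1 reversed. The reversed one is the split of genes changed at least 2-fold under red light, from 40.2% to 57.4% higher with ratios centred on their median, which follows from shifting every ratio by the median of -0.26 under a fixed bound. A q-value under 0.01 left 512 falls under blue light, 436 rises under red light, 569 shared genes (295 rises and 274 falls) and 16 risen chloroplast genes under red light. A change of at least 2-fold left 554 falls under blue light, 787 falls under red light and 276 shared falls. These counts are smaller by construction. Limiting chloroplast loci to those of at least 300 bp with 1 gene left 6 rises under blue light, also by construction. With no filter, the median log2 ratio of chloroplast genes under red light moved from 2.53 to 0.57, because IDs that the authors did not test entered; it was 2.21 for those tested in the blue comparison. With no filter, the correlation of the responses fell from 0.66 to 0.60. The minimum mean FPKM of 10 says nothing about stability: it removed 0 tested genes of the blue and 1 of the red comparison. Of 29 results picked by the rule for named genes and from the ID lists, not all printed above, 5 did not pass 0.01. All 29 held with Benjamini-Hochberg values computed again. They include the largest falls under red light among IDs in the reference table with a ratio, CMA021C and CME102C, each with a log2 ratio of -3.57.

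No paired analysis was possible because the deposited table has no values per library. For the same reason leaving out each replicate, DESeq2, a fit to the compared groups alone, camera and fry were not run. Pseudocounts and the absence of a filter do not bear on calls made from the authors' q-values and were not run for them, and the lists by ID share no gene. Depth is unknown, so what it limits cannot be stated.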

Other observations

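Genes that passed the threshold under red light began from different dark levels. The 656 genes that rose were lower in the dark control of the red experiment than in that of the blue experiment by a median of -0.73 on the log2 scale, and the 1186 that fell were higher by 0.59. For 962 genes that rose under blue light, the corresponding median was 0.11. These values have no test, and a gene's own dark level enters both the ratio and this difference, which alone brings such a relation.

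The 244 IDs on the chloroplast held 7.33% of the summed FPKM in the dark control of the blue experiment, 8.88% under blue light, 6.50% in the dark control of the red experiment and 14.2% under red light. Much of this is 1 short chloroplast ID, EPlCMEG00000000015, with a locus of 92 bp. It stood at 94404 FPKM under red light, against 39301 in its dark control, and at 49091 under blue light, against 26112. Its q in the authors' deposited table was 0.228 under red and 0.233 under blue light, past no threshold used here, so these shares do not measure the chloroplast genes as a group.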
